A study of Homo sapiens with 12 samples.

How the data were processed

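The 12 libraries were RNA-seq of A375 human melanoma cells infected with a lentiviral non-targeting shRNA (shNT) or an shRNA against INO80 (shIno80), in 6 groups of 2 libraries (2, 3 and 4 days after infection). Per the submitters' processing notes, total RNA was made into libraries with a TruSeq kit and processed with TopHat2 2.0.4 and Cufflinks 2.0.2 on hg19; the notes do not say what each tool did. The deposited value per RefSeq accession is FPKM (fragments per kilobase of transcript, scaled by the mapped fragments of the library), per the labels, and the values were checked for this unit. The files hold no counts, so sequencing depth is unknown and no counting interval is given. The series text also mentions ChIP-seq, which was not analysed here.

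Each file held 40723 accessions. Of these 39397 were paired with a gene symbol by a RefSeq table and 493 by GENCODE 29 alone; 833 without a symbol (0.566% to 1.80% of FPKM per library) were left out of the gene values. FPKM was summed per gene, giving 23190 genes, of which 7851 summed 2 or more accessions. Genes with at least 1 FPKM in at least 2 of the 12 libraries were tested (12857 genes) on log2(FPKM + 1), with no further scaling between libraries.

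Differences were tested with limma 3.58.1 (limma-trend, moderated tests, two-sided) in R 4.3.3, in a fit of the 6 group means with 6 residual degrees of freedom and 2.4 prior degrees of freedom. The contrasts were shIno80 against shNT on each day and averaged over the 3 days, day 4 against day 2 within each arm, and the differences between days of the shIno80 effect, with a moderated F test over both of these differences. P-values were adjusted by Benjamini-Hochberg over the genes of a contrast, with a threshold of 0.05. Replicate numbers were not used to pair the libraries in this fit. Deviations of libraries with the same number correlated between groups with a median of 0.038. Over the 15 pairs of groups these correlations ran from -0.147 to 0.225, and 3 were over 0.1, so some pairing was not excluded. The fit was tested on simulated data with the mean and spread of each gene: averaged over days, 82% of genes with a log2 change of 0.25 were found, 96% at 0.5, 98% at 1 and 100% at 2 (50 genes each), against 18%, 88%, 96% and 98% on day 2 alone, and 6 of 12607 unchanged genes were called. Changes were planted only in genes with a mean log2(FPKM + 1) above 2, so these rates do not cover lower genes. The simulated noise was independent between genes.

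The gene lists (38), the contrasts, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The lists cover chromatin remodellers, transcription and splicing, melanoma states, growth signalling, cell cycle, DNA repair, stress, immunity, metabolism, translation, matrix and adhesion, cell death, RNA interference, housekeeping genes and markers of other cell types. Each list was tested with camera (preset inter-gene correlation 0.01), with camera using an estimated correlation, and with fry (both with the mean-variance trend), adjusted over the 38 lists within a contrast; fry tests whether the genes move on balance one way and does not compare them with other genes. Counts of changed members are given over all genes and adjusted over the list alone. Named genes were INO80, MITF, SOX10, SOX9, JUN, FOSL1, MYC and AXL, plus the 10 largest rises and 10 largest falls of the averaged contrast (adjusted p under 0.05, same sign on all 3 days, at least 5 FPKM in the higher arm). In every other contrast they were the 5 largest rises and falls whose libraries did not overlap, with at least 5 FPKM, or for the F test the 5 smallest p-values. Up to 4 members per list with the smallest averaged p-value completed the rule, and symbols of small RNAs and uncharacterised loci were left out. For most lists 2 to 4 of these members are named in the text.

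After the data were seen, 3′UTRs were searched for short sequences. One GENCODE transcript per gene was used, with a 3′UTR of at least 50 bases (11372 genes). Log2 changes were clipped at 2 in either direction. They were adjusted by regression for log2 3′UTR length and base composition (share of G and C), each with its square, and for log2 expression. The 7-base sequences present in at least 50 of 5686 randomly drawn genes were scored, and the lowest and highest were measured in the remaining 5686 genes by match type: 8 bases, 7 bases in either register, or 6 bases. Groups were compared by a permutation test with 100000 permutations.

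Alternatives were a pseudocount of 0.1 or 5, no filter or a filter of 5 FPKM, quantile normalization, median ratio scaling, TPM, the replicate number as a block, limma without trend, robust empirical Bayes, each library left out in turn, only the 4 libraries compared, and a 2-fold threshold. Added after seeing the data were tests per accession, tests without small RNA genes, without genes whose 3′UTR holds 6 bases of the sequence found, and without the 2 libraries with the highest small RNA share. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.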

Results

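Gene expression was measured by RNA-seq in 12 libraries of A375, an established human melanoma cell line. Cells received a lentiviral short hairpin RNA (shRNA) directed at INO80 (shIno80) or a non-targeting shRNA (shNT) and were harvested 2, 3 or 4 days later, with 2 libraries in each of the 6 groups. INO80 is the ATPase of a chromatin remodelling complex, and the series asks what it does in the transcription of melanoma oncogenes. Each shIno80 group was compared with the shNT group of the same day, so no control library served for more than 1 day. The files hold FPKM without counts, so the sequencing depth of each library is unknown. Total FPKM ran from 418116 in shIno80 day 4 replicate 2 to 480348 in shIno80 day 2 replicate 1, and 11793 to 12311 genes per library reached 1 FPKM. Small RNA genes took 5.37% (shNT day 4 replicate 1) to 12.2% (shIno80 day 3 replicate 2) of all FPKM, and the precursor RNA of the large ribosomal RNAs, RNA45SN5, was listed at 0 in 7 of the 12 libraries. Log2 changes below are on the log2(FPKM + 1) scale, which understates the change of genes with low values, and the SD and SE of a gene rest on n = 2 libraries per group, while the SE of a comparison of 3′UTR matches is over genes, which are not independent replicates. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these libraries only.

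INO80 mRNA was lower in shIno80 than in shNT cells on every day. In shNT cells it stood at 9.97 and 10.5 FPKM on day 2, 8.81 and 8.62 on day 3, and 7.40 and 7.71 on day 4. In shIno80 cells it stood at 3.16 and 2.98 FPKM on day 2, 1.62 and 1.77 on day 3, and 1.40 and 1.42 on day 4. The log2 change was -1.47 on day 2 (adjusted p = 1.12e-06), -1.85 on day 3 (adjusted p = 3.69e-07) and -1.83 on day 4 (adjusted p = 4.45e-07). Averaged over the days it was -1.71 (SE 0.030, adjusted p = 7.09e-09), a 4.29-fold lower mean FPKM (8.84 against 2.06), and the libraries of the arms did not overlap. INO80 also fell with time in shNT cells (log2 change -0.39, adjusted p = 0.000193).

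**Figure D1:**
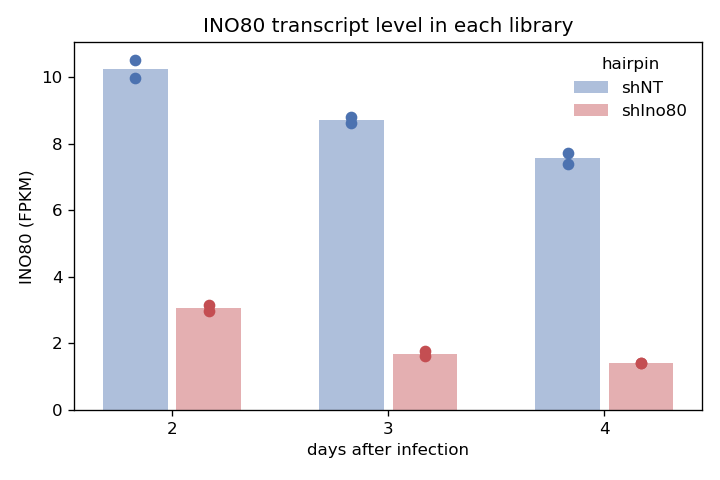
INO80 FPKM in each of the 12 libraries (points) with the group means (bars starting at 0), by day and shRNA. The shIno80 libraries lie between 1.40 and 3.16 FPKM and the shNT libraries between 7.40 and 10.5 FPKM.

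Time after infection and the shRNA both separated the libraries. The first principal component held 38.1% of the variance and ordered the days within each arm, from -53.6 and -49.5 in shNT day 2 to 47.2 and 46.4 in shIno80 day 4. On this axis shIno80 day 3 (21.5 and 23.9) lay beside shNT day 4 (19.2 and 20.2). The second component held 18% and parted the arms, with shNT libraries from 1.75 to 37.6 and shIno80 libraries from -29.2 to -11.5. Replicates correlated across genes with Pearson r from 0.946 (shIno80 day 3) to 0.968 (shNT day 2); genes are not independent replicates.

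**Figure D2:**
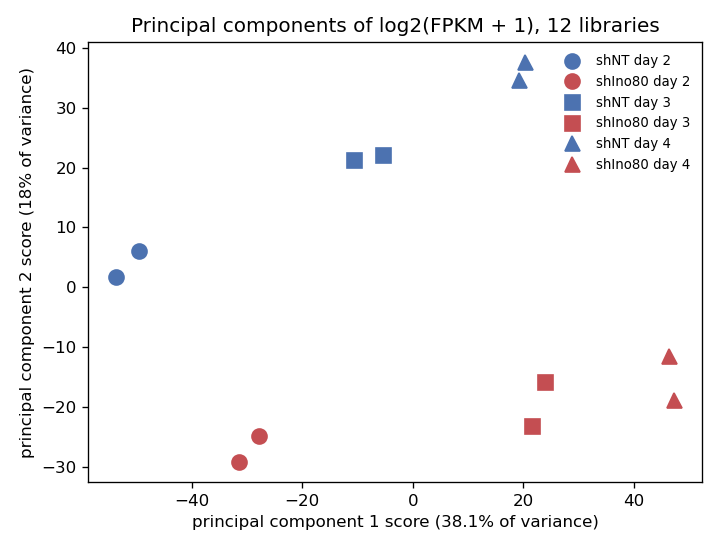
The 12 libraries on the first 2 principal components of log2(FPKM + 1), which hold 38.1% and 18% of the variance, coloured by shRNA and marked by day. Days run along the first axis in both arms, and the second axis parts shNT from shIno80.

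Averaged over the 3 days, AREG, STC1 and MMP10 rose most in shIno80 cells. AREG, a ligand of the EGF receptor, was 7.51-fold higher (mean FPKM 8.88 against 66.7, log2 change 2.58, SE 0.155, adjusted p = 1.83e-06), and reached 127 ± 25.1 FPKM on day 4 against 16.3 ± 8.13 in shNT cells. STC1, the secreted glycoprotein stanniocalcin-1, was 5.85-fold higher (log2 change 2.38, adjusted p = 5.89e-07). MMP10, a matrix metalloprotease, was 14.0-fold higher (log2 change 2.31, adjusted p = 1.19e-06), with 4.47 ± 0.425 FPKM in shNT and 60.0 ± 12.2 in shIno80 cells on day 4. CD55, which protects cells from complement, was 4.02-fold higher (76.9 against 309 FPKM, log2 change 2.10, SE 0.040, adjusted p = 1.01e-08). The other genes of the 10 largest rises were CEACAM1 (log2 change 2.03), SERPINB2 (2.02), PTHLH (2.02), RGS2 (1.97), ACP3 (1.90) and BMP6 (1.80), with adjusted p from 2.96e-08 to 0.000124.

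The largest falls included a hair keratin, caveolin-1 and thrombospondin-1. KRT81 was 8.09-fold lower (41.4 against 5.11 FPKM, log2 change -2.81, SE 0.126, adjusted p = 4.08e-07). CAV1, the main coat protein of caveolae, was 6.23-fold lower (log2 change -2.73, SE 0.043, adjusted p = 4.2e-09) and went from 108 ± 5.97 FPKM in shNT to 21.9 ± 0.117 in shIno80 cells on day 2. PIR was 7.99-fold lower (log2 change -2.58, adjusted p = 3.99e-08) and FAM162A 6.17-fold lower (log2 change -2.50, adjusted p = 1.31e-08). THBS1, a secreted matrix glycoprotein, was 4.54-fold lower (226 against 49.8 FPKM, log2 change -2.35, adjusted p = 6.03e-06). NGFR, a receptor for neurotrophins and a marker of neural crest-like melanoma cells, was 7.62-fold lower (log2 change -2.16, adjusted p = 1.17e-06). The rest of the 10 largest falls were CPA4 (log2 change -2.43), the lysosomal enzyme PPT1 (-2.34), IL37 (-2.25) and IGFBP5 (-2.13), with adjusted p from 4.2e-09 to 0.000294. Matches of 7 or 8 bases to the sequence CCATTTCA, described with the 3′UTRs at the end, lay in the 3′UTRs of CAV1, FAM162A, PIR, CPA4, PPT1 and IGFBP5 among these genes and in those of CD55, RGS2 and BMP6 among the rises.

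**Figure D3:**
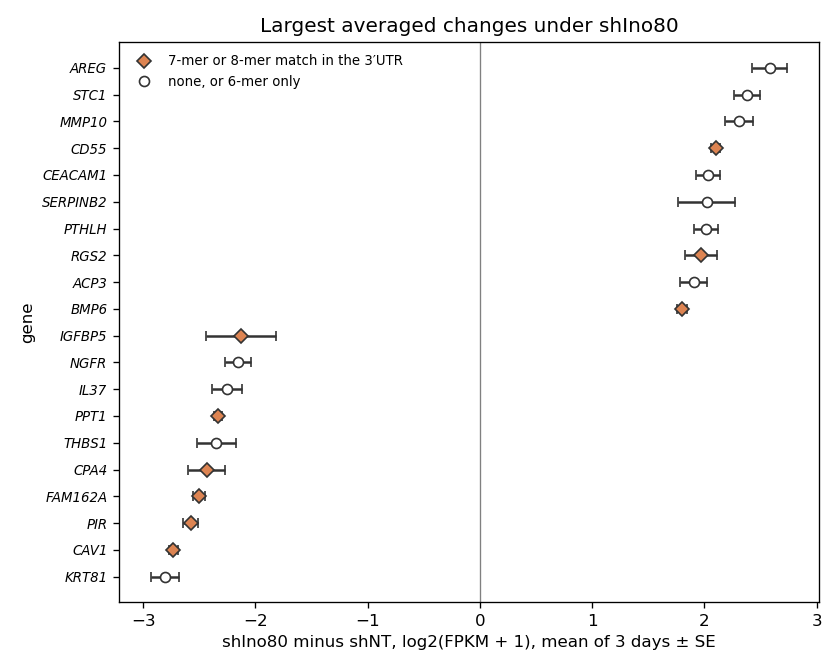
Log2 change, averaged over the 3 days, of the 10 largest rises and 10 largest falls. The rule that chose these genes required the same sign on all 3 days. The changes on day 4 alone, -4.07 for KRT81 and 3.46 for MMP10, are given in the text and differ from these averages.

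Genes of the dedifferentiated, invasive melanoma state were mostly lower. Of 30 measured members 21 fell and 3 rose (median log2 change -0.52, camera adjusted p = 0.00135; adjusted p = 0.501 with an estimated correlation). Without genes holding the 6 bases CATTTC in the 3′UTR, an alternative chosen after seeing the data, the median was -0.24 and the call was lost (adjusted p = 0.0846). Besides NGFR and IL6 they included LOXL2 (-0.72), TNC (-0.57), TGFBI (-0.99) and the receptor tyrosine kinase AXL (84.4 against 48.5 FPKM, log2 change -0.77, adjusted p = 0.000109). The pigmentation programme, of which 13 of 26 listed genes were measured, had 4 rises, among them APOD (1.38) and RAB38 (0.55), and 5 falls (camera adjusted p = 0.606). Its master regulator MITF was slightly lower (log2 change -0.18, adjusted p = 0.00434), and SOX10, which drives melanocyte identity, was higher (161 against 198 FPKM, log2 change 0.29, adjusted p = 7.98e-05). Neural crest and melanoma regulators had 4 rises and 15 falls of 28 (camera adjusted p = 0.134), among them TFAP2C (-0.58). Melanoma and testis antigens had 5 rises, such as MIA (0.44), and 6 falls, such as PRAME (-0.25), of 20; their median was 0.012, their mean -0.051, and camera gave the direction down (adjusted p = 0.606). SOX9, at 0.207 to 0.396 FPKM, was too low to be tested, and MYC gave a log2 change of 0.019 (adjusted p = 0.867). Counts adjusted over the list alone were the same for these lists except 3 rises for the neural crest list. Of the dedifferentiated list 10 of 29 searched members held a 7- or 8-base match to CCATTTCA in the 3′UTR (34.5%, against 26.7% of all 11372 genes searched), LOXL2 and TNC among them.

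Growth-signalling genes went both ways. Output genes of the MAPK pathway, which the BRAF-mutant A375 line depends on, had 5 rises and 14 falls of 23 (median -0.44, camera adjusted p = 0.0668, and 0.036 with the replicate number as a block), and 10 of 22 searched members held a 3′UTR match (45.5%). HMGA2 (-0.80), LIF (-0.87) and PHLDA2 (-0.83) fell, EPHA4 (0.92) rose, and FOSL1 was lower (150 against 110 FPKM, log2 change -0.45, adjusted p = 0.0064). AP-1 and immediate early genes had 18 rises and 2 falls of 22 (median 0.43, camera adjusted p = 0.00184; adjusted p = 0.501 with an estimated correlation), with NR4A2 (1.33), BTG2 (1.43) and the phosphatase DUSP1 (0.92) among the rises. JUN itself gave an averaged log2 change of -0.028 (adjusted p = 0.802). YAP and TEAD targets had 3 rises and 12 falls of 22 (median -0.29, camera adjusted p = 0.0374; adjusted p = 0.665 with an estimated correlation), with MYOF (-0.87) down and LATS2 (0.79) up. This call was lost with a filter of 5 FPKM (adjusted p = 0.122) and without shNT day 2 replicate 1 (0.0584), shIno80 day 2 replicate 2 (0.0605), shNT day 3 replicate 1 (0.0592), shIno80 day 3 replicate 2 (0.0567) or shIno80 day 4 replicate 2 (0.0538). Extracellular matrix and TGF-beta targets had 7 rises, such as COL6A1 (0.69), and 15 falls, such as COL5A1 (-1.22), of 31 (camera adjusted p = 0.0901, and 0.0294 with no filter). Adhesion receptors had 10 rises and 14 falls of 29 (camera adjusted p = 0.168), with N-cadherin, CDH2 (-0.69), and MCAM (-1.29) among the falls. Counts adjusted over the list alone were identical for these 5 lists.

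Cell cycle genes were lower nearly throughout. Of 40 mitosis and G2/M genes 37 fell (median log2 change -0.57, camera adjusted p = 2.85e-07; adjusted p = 0.596 with an estimated correlation). The spindle checkpoint gene MAD2L1 was at -1.31 and BUB3 at -0.58. Of 42 DNA replication and G1/S genes 38 fell (median -0.48, camera adjusted p = 2.85e-07; adjusted p = 0.596 with an estimated correlation), including the helicase subunit MCM2 (40.8 against 17.6 FPKM, log2 change -1.30), thymidine kinase TK1 (-1.40) and cyclin CCNE1 (-0.43). DNA repair genes had 4 rises, such as LIG4 (0.61), and 26 falls, such as PARP2 (-0.91), of 40 (camera adjusted p = 0.00308; adjusted p = 0.596 with an estimated correlation). Targets of p53 had 15 rises and 5 falls of 33 (camera adjusted p = 0.0654), with the death genes BBC3 (0.83) and FAS (0.86) up and PHLDA3 (-0.96) down. This list was called with no filter (0.0173), under quantile normalization (0.0496), with the replicate number as a block (0.0481), and without shNT day 3 replicate 1 (0.0434), shIno80 day 3 replicate 2 (0.0378), shNT day 4 replicate 1 (0.0239) or shIno80 day 4 replicate 2 (0.0256). Apoptosis regulators had 14 rises and 7 falls of 29 (camera adjusted p = 0.207), with the survival gene MCL1 (167 against 311 FPKM, log2 change 0.88) up and BCL2L2 (-0.76) down. Counts adjusted over the list alone differed only for DNA repair, with 27 falls. A 3′UTR match lay in 5 of 40 mitosis genes (12.5%) and 10 of 41 replication genes (24.4%).

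Energy and lipid metabolism genes were lower. Glycolysis and hypoxia genes had 26 falls and 2 rises of 33 (median -0.43, camera adjusted p = 8.48e-07; adjusted p = 0.501 with an estimated correlation), with hexokinase HK1 at -0.71, PFKFB4 at -1.15 and enolase ENO1 at 1140 against 778 FPKM (log2 change -0.63). Oxidative phosphorylation genes had 32 falls, such as NDUFA9 (-0.91) and NDUFV2 (-0.52), and 3 rises, with COX7C at 0.85, of 49 (camera adjusted p = 7.84e-06; adjusted p = 0.596 with an estimated correlation). Cholesterol synthesis had 18 falls and 3 rises of 24 (camera adjusted p = 0.00135; adjusted p = 0.501 with an estimated correlation), including MSMO1 (-1.01) and the transcription factor SREBF2 (-0.82). Fatty acid synthesis had 13 falls and 3 rises of 19 (camera adjusted p = 0.00864; adjusted p = 0.501 with an estimated correlation), including the desaturase FADS1 (46.8 against 16.5 FPKM, log2 change -1.44), ACLY (-0.40) and malic enzyme ME1 (-0.84). NRF2 and antioxidant genes had 13 falls and 2 rises of 23 (camera adjusted p = 0.00636; adjusted p = 0.501 with an estimated correlation), NQO1 (-0.46) among them. Autophagy and lysosome genes instead had 24 rises and 5 falls of 34 (median 0.27, camera adjusted p = 0.0045; adjusted p = 0.596 with an estimated correlation), with the cathepsin CTSL (74.8 against 192 FPKM, log2 change 1.28) and the kinase ULK1 (0.71) up and LAMP2 (-0.65) down. For all 6 of these lists counts adjusted over the list alone were identical. HK1, NDUFA9, MSMO1, FADS1 and LAMP2 held a 3′UTR match.

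Stress and immune lists differed from each other. Heat shock genes had 12 falls, including the chaperones HSPE1 (-0.45) and HSP90AA1 (-0.40), and 1 rise of 16 (camera adjusted p = 0.00184; adjusted p = 0.501 with an estimated correlation). Unfolded protein response and ATF4 targets had 9 rises and 12 falls of 34 (camera adjusted p = 0.606), with HERPUD1 (0.80) up and the serine synthesis enzyme PSAT1 (-1.19) down. NF-kB and inflammatory genes had 5 rises and 12 falls of 26 (median -0.25, camera adjusted p = 0.0807, but 0.0481 with the replicate number as a block and 0.0337 without shNT day 2 replicate 2). The chemokine CXCL1 fell (511 against 143 FPKM, log2 change -1.64, SE 0.117, adjusted p = 4.71e-06), as did CCL2 (-1.27) and TNFAIP2 (-0.86). Interferon-stimulated genes had 17 rises, such as IRF7 (1.11) and STAT2 (0.41), and 7 falls, such as IFIT5 (-0.57), of 39 (camera adjusted p = 0.265). Antigen presentation, with 7 of 21 listed genes measured, had 4 rises, such as NLRC5 (0.66) and B2M (0.27), and 1 fall (camera adjusted p = 0.352). Counts adjusted over the list alone did not differ for these lists.

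Lists for chromatin, transcription and translation went in different directions. The 15 INO80 complex subunits had 6 rises, such as NFRKB (0.39), and 7 falls; after INO80 itself, the shared helicase RUVBL1 was at 63.2 against 33.0 FPKM (log2 change -0.92). Their median was 0.053, their mean -0.15, and camera gave the direction down (adjusted p = 0.689). SRCAP and TIP60 subunits had 10 rises, such as BRD8 (0.38), and 4 falls, such as MORF4L1 (-0.82), of 17, with a median of 0.11, a mean of -0.005, the direction up by camera (adjusted p = 0.602) and down by fry (adjusted p = 0.0327). SWI/SNF, ISWI and CHD remodellers had 11 rises, such as SMARCD1 (0.53), and 7 falls, such as SMARCD2 (-0.54), of 23 (camera adjusted p = 0.606). Mediator and BET coactivators had 18 rises, such as CDK7 (0.47) and MED15 (0.42), and 3 falls of 35 (camera adjusted p = 0.0577, but 0.011 with no filter, 0.0477 with a filter of 5 FPKM and 0.046 without shIno80 day 4 replicate 2). RNA polymerase II and splicing factors had 27 falls, such as SF3B2 (-0.74) and SF3B3 (-0.43), and 2 rises of 41 (camera adjusted p = 0.000386; adjusted p = 0.501 with an estimated correlation). Ribosome biogenesis genes had 23 falls, such as NCL (-0.78) and NOLC1 (-0.51), and 4 rises of 40 (camera adjusted p = 0.00135; adjusted p = 0.638 with an estimated correlation). Cytosolic ribosomal proteins had 14 rises, such as RPL13A (0.56), and 24 falls, such as RPL22 (-0.72), of 68 (camera adjusted p = 0.332). RNA interference genes had 7 rises, including DICER1 (0.43) and AGO2 (0.71), and 3 falls of 13 (camera adjusted p = 0.265). Mediator had 17 rises and ribosomal proteins 13 when adjusted over the list alone, and the other counts were the same. MORF4L1, NCL, NOLC1, RPL22, SF3B2 and SF3B3 held a 3′UTR match.

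The marker lists of other cell types did not pass the camera threshold averaged over days, while fry called fibroblast markers (median -0.37, adjusted p = 0.000495) and blood and immune markers (median 0.34, adjusted p = 0.0232). Keratinocyte and epithelial markers, with 11 of 23 measured, had 5 rises, such as KRT15 (0.97) and DSP (0.75), and 5 falls; their median was -0.22, their mean 0.050, and camera gave the direction down (adjusted p = 0.845) where fry gave up (adjusted p = 0.54). Of 8 fibroblast markers measured 5 fell, such as FAP (-0.41) and LUM (-0.44) (camera adjusted p = 0.0746); on day 4 camera gave 0.0677, but 0.043 with the replicate number as a block and 0.0353 under TPM, and on day 3 it gave 0.0821, but 0.049 without genes holding CATTTC. Of the 4 blood and immune markers measured, LYZ (0.82) and CD68 (0.87) rose and 1 fell (camera adjusted p = 0.754). The 4 endothelial markers measured lay between log2 changes of -0.32 and 0.059 (camera adjusted p = 0.845), and no member passed the threshold by limma. Housekeeping genes had 9 rises, such as GUSB (0.34), and 13 falls, such as SDHA (-0.35), of 25 (camera adjusted p = 0.356). The fall count of blood and immune markers was 2 when adjusted over the list alone, and the other counts did not differ.

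Over all genes, 9113 of 12857 (70.9%) changed averaged over days, 4758 up and 4355 down, of which 83 rose and 178 fell at least 2-fold; under median ratio scaling 4479 rose and 4602 fell. Camera called 2 lists up and 13 down, of which 0 were called with an estimated correlation (1 at an unadjusted p under 0.05), while fry called 32. Without genes whose 3′UTR holds the 6 bases CATTTC, an alternative chosen after seeing the data, 5 calls were lost. The median went from -0.52 to -0.24 for the dedifferentiated state (adjusted p = 0.0846), from -0.33 to -0.24 for cholesterol synthesis (0.0503) and from -0.23 to -0.11 for NRF2 (0.0592). It stayed at -0.27 for fatty acid synthesis (0.117) and went from -0.29 to -0.32 for YAP and TEAD targets (0.0592), with fewer genes tested.

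On day 2 the receptor NGFR, pirin and caveolin-1 were already among the largest falls. PIR (log2 change -2.66, adjusted p = 3.49e-06), NGFR (-2.32, adjusted p = 9.64e-05), CAV1 (-2.25, adjusted p = 7.88e-07), FAM162A (-2.19, adjusted p = 2.48e-06) and BANF1, a DNA-binding protein of the nuclear envelope (158 ± 1.34 against 36.4 ± 1.48 FPKM, log2 change -2.09, adjusted p = 2.66e-07), fell most. CD55 (28.1 ± 1.13 against 138 ± 9.45 FPKM, log2 change 2.25, adjusted p = 6.49e-07), STC1 (2.11, adjusted p = 0.000123), SERPINB2 (1.80, adjusted p = 0.012), AREG (1.78, adjusted p = 0.00126) and SMOC1 (1.68, adjusted p = 0.000165) rose most. Heat shock genes (12 falls and 1 rise of 16, camera adjusted p = 0.00022; adjusted p = 0.568 with an estimated correlation) and replication genes (18 falls of 42, camera adjusted p = 0.000224; adjusted p = 0.848 with an estimated correlation; fry adjusted p = 0.0748) were lower. So were genes of the dedifferentiated state (13 falls and 1 rise of 30, camera adjusted p = 0.000881; adjusted p = 0.568 with an estimated correlation) and MAPK output genes (11 falls and 2 rises of 23, camera adjusted p = 0.011; adjusted p = 0.568 with an estimated correlation; median -0.37, and -0.26 with adjusted p = 0.157 without genes holding CATTTC in the 3′UTR). Ribosomal protein genes were higher (15 rises and 1 fall of 68, median 0.15, camera adjusted p = 0.00183; adjusted p = 0.848 with an estimated correlation; fry adjusted p = 0.203), and under quantile normalization their median was 0.019 (adjusted p = 0.803). Adjusted over the list alone, falls numbered 13 for heat shock, 18 for replication, 15 for the dedifferentiated state and 12 for MAPK output, and 5 ribosomal protein genes rose. In all 5210 genes changed (40.5%), 2474 up and 2736 down (2789 and 2310 under quantile normalization), with 43 rises and 111 falls of at least 2-fold; camera called 3 lists up and 11 down, and 0 with an estimated correlation (3 at an unadjusted p under 0.05), against 17 by fry. Without shNT day 2 replicate 1 the count was 3387 and without shIno80 day 2 replicate 2 it was 3412; SERPINB2 lost its call without shNT day 2 replicate 2 (adjusted p = 0.0788) or without shIno80 day 2 replicate 1 (adjusted p = 0.0753).

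On day 3 MMP10 gave the largest rise and KRT81 the largest fall. MMP10 (log2 change 3.04, adjusted p = 2.06e-05), AREG (6.08 ± 0.0527 against 55.8 ± 1.29 FPKM, log2 change 3.00, adjusted p = 5.19e-05), PI3, an elastase inhibitor (12.2 ± 11.8 against 69.5 ± 48.9 FPKM, log2 change 2.59, adjusted p = 0.0236), STC1 (2.54) and SERPINB2 (2.47) rose most. KRT81 (48.3 ± 0.167 against 4.78 ± 0.235 FPKM, log2 change -3.10), CAV1 (-2.99), PIR (-2.85), CPA4 (-2.70) and THBS1 (-2.57) fell most. Replication genes (38 falls of 42, median -0.64, camera adjusted p = 2.73e-08; adjusted p = 0.576 with an estimated correlation) and mitosis genes (32 falls of 40, median -0.66, camera adjusted p = 3.19e-07; adjusted p = 0.576 with an estimated correlation) were lower. The same held for glycolysis genes (25 falls and 2 rises of 33, camera adjusted p = 3.62e-07; adjusted p = 0.412 with an estimated correlation) and cholesterol synthesis genes (18 falls and 1 rise of 24, median -0.57, camera adjusted p = 3.17e-05; adjusted p = 0.412 with an estimated correlation). Adjusted over the list alone, there were 40 falls for replication, 34 for mitosis, 25 for glycolysis and 18 for cholesterol synthesis, with 3 rises in the last. In all 7088 genes changed (55.1%), 3598 up and 3490 down (3460 and 3619 under median ratio scaling, 3385 and 3419 under TPM, 3686 and 3757 with no filter, 2752 and 2781 without shNT day 3 replicate 1), with 128 rises and 266 falls of at least 2-fold; camera called 3 lists up and 12 down, and 0 with an estimated correlation (2 at an unadjusted p under 0.05), against 30 by fry. PI3 lost its call with robust empirical Bayes (adjusted p = 0.0552), without shNT day 3 replicate 2 (adjusted p = 0.154) and without shIno80 day 3 replicate 1 (adjusted p = 0.146).

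On day 4 CA9, IL6 and IL37 were among the 5 largest falls. CA9, a carbonic anhydrase induced by hypoxia (17.9 ± 16.7 against 0.0598 ± 0.0596 FPKM, log2 change -3.81, adjusted p = 0.000948), the cytokine IL6 (20.4 ± 12.6 against 1.06 ± 0.991 FPKM, log2 change -3.32, adjusted p = 0.00186) and IL37 (71.2 ± 11.9 against 7.54 ± 1.74 FPKM, log2 change -3.08, adjusted p = 1.89e-05) fell along with KRT81 (-4.07, adjusted p = 5.19e-06) and CAV1 (-2.95, adjusted p = 1.85e-07). CXCL1 went from 790 ± 33.5 to 150 ± 3.79 FPKM. MMP10 (log2 change 3.46, adjusted p = 1.03e-05), AREG (2.96), STC1 (2.48), CEACAM1 (2.41) and PTHLH (2.29) rose most. Mitosis genes (39 falls of 40, median -0.88, camera adjusted p = 5.67e-10; adjusted p = 0.576 with an estimated correlation) and glycolysis genes (27 falls and 1 rise of 33, median -0.68, camera adjusted p = 5.67e-10; adjusted p = 0.464 with an estimated correlation) were lower. NF-kB and inflammatory genes were lower too (11 falls and 2 rises of 26, camera adjusted p = 0.0217; adjusted p = 0.611 with an estimated correlation), while AP-1 and immediate early genes were higher (18 rises and 1 fall of 22, median 0.68, camera adjusted p = 0.00206; adjusted p = 0.567 with an estimated correlation). Without genes holding CATTTC in the 3′UTR these 2 calls were lost, with a median of -0.31 in place of -0.40 (adjusted p = 0.147) and of 0.62 in place of 0.68 (0.0566). Ribosomal protein genes were now lower (41 falls and 1 rise of 68, median -0.31, camera adjusted p = 4.67e-08; adjusted p = 0.611 with an estimated correlation), with a median of -0.067 under quantile normalization (adjusted p = 0.151). Adjusted over the list alone there were 28 falls for glycolysis, 42 for ribosomal proteins and 19 rises for AP-1, and the other counts of this day given here were the same. In all 7644 genes changed (59.5%), 4218 up and 3426 down, with 180 rises and 348 falls of at least 2-fold; camera called 4 lists up and 13 down, and 0 with an estimated correlation (1 at an unadjusted p under 0.05), against 30 by fry. With values rescaled to a fixed sum per library (TPM), which took the median of all genes on this day from 0.037 to 0.13, 5166 genes rose and 2660 fell, and under median ratio scaling 3697 rose and 3887 fell.

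**Figure D4:**
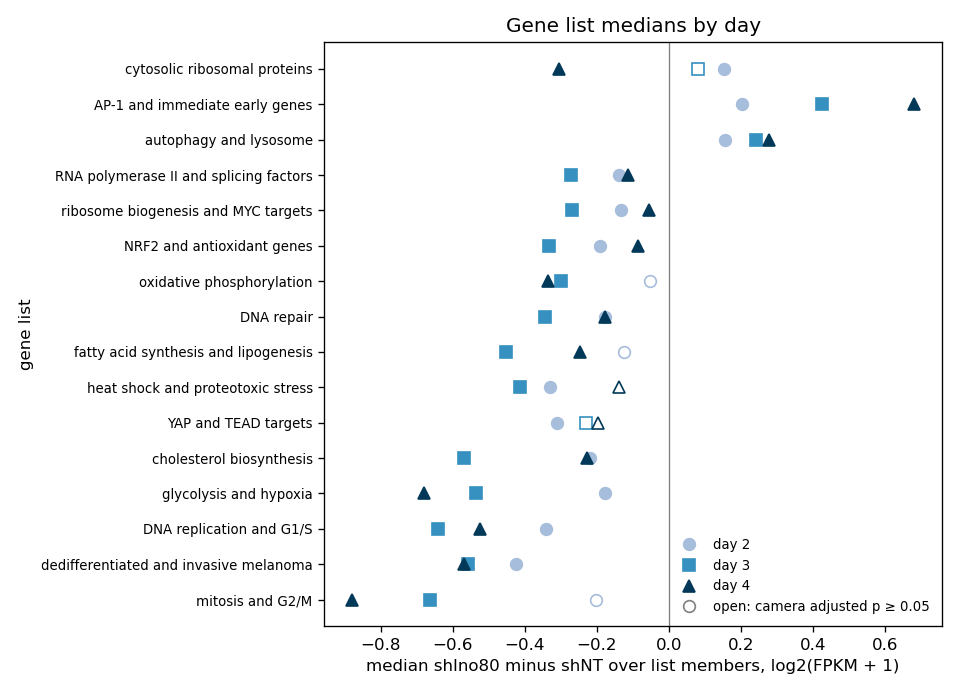
Median log2 change at day 2, day 3 and day 4 (shIno80 against shNT) of the 15 gene lists, of 38, that camera called averaged over days. The ribosomal protein list, which was not called averaged over days, is added. Mitosis genes go from -0.20 on day 2 to -0.88 on day 4, and ribosomal protein genes from 0.15 to -0.31 (0.019 to -0.067 under quantile normalization).

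The 3 days called many genes in common. Days 2 and 3 shared 2134 rises and 2234 falls (692 and 743 if independent), with 8 and 15 genes called in opposite directions. Days 3 and 4 shared 3031 rises and 2691 falls (1180 and 930 if independent), with 13 and 19 in opposite directions. Days 2 and 4 shared 1942 and 1851 (812 and 729 if independent), with 66 and 128 in opposite directions. The values if independent do not allow for the spread of each gene, which was estimated once for all contrasts and by itself favours shared calls. At all 3 days 1866 genes rose and 1787 fell. Across genes, which are not independent replicates, the effects of days 2 and 3 correlated with Pearson r 0.494 and Spearman rho 0.82, those of days 2 and 4 with 0.492 and 0.663, and those of days 3 and 4 with 0.525 and 0.845. Without small RNA genes, an alternative chosen after seeing the data, these Pearson values were 0.847, 0.69 and 0.882.

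For some genes the shIno80 effect depended on the day. ARHGAP19 was lower on day 2 (8.42 ± 0.0284 against 4.55 ± 0.101 FPKM) and higher on day 4 (4.74 ± 0.106 against 7.16 ± 0.492; F test adjusted p = 0.000355). APOE, an apolipoprotein, rose with time in shNT cells to 9.83 ± 0.403 FPKM on day 4 and stood at 1.03 ± 0.0781 in shIno80 cells (adjusted p = 0.000392). PLOD2, a collagen-modifying enzyme (adjusted p = 0.000441), the ribosomal protein gene RPL22 (191 ± 3.55 against 75.1 ± 4.2 FPKM on day 4, adjusted p = 0.00103) and EEF1A2 (68.6 ± 1.73 against 15.8 ± 1.49 FPKM on day 4, adjusted p = 0.00103) completed the 5 smallest p-values. JUN was lower on day 2 (log2 change -0.79, adjusted p = 0.0056) and higher on day 4 (0.74, adjusted p = 0.00419). From day 2 to day 4 the effect moved down for ribosomal proteins (46 of 68 genes, median -0.45, or -0.097 under quantile normalization, camera adjusted p = 8.66e-24; adjusted p = 0.595 with an estimated correlation; fry adjusted p = 0.0149). It also moved down for glycolysis (20 of 33 genes, median -0.53, camera adjusted p = 1.41e-13; adjusted p = 0.232 with an estimated correlation; fry adjusted p = 0.00153). These counts were 56 and 24 adjusted over the list alone. The F test called 1743 genes in all, and 2680 with the replicate number as a block. It called 339 genes without shNT day 2 replicate 1, 558 without shNT day 2 replicate 2, and 479 and 438 without shIno80 day 2 replicates 1 and 2. It called 1005 and 1101 without shNT day 3 replicates 1 and 2, 985 and 1027 without shIno80 day 3 replicates 1 and 2, 1072 without shIno80 day 4 replicate 1, and 3041 under TPM.

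Control cells changed with time after infection. From day 2 to day 4 in shNT cells, the cytokine IL1B rose from 5.59 ± 1.21 to 240 ± 80.6 FPKM (log2 change 5.16, SE 0.447, adjusted p = 1.7e-05), and complement C3 from 20.2 ± 0.438 to 298 ± 0.258 (3.82, adjusted p = 1.18e-07). PI3 (4.71), IL37 (4.49) and the metabolic regulator TXNIP (3.92) were the other largest rises. The anaphase activator CDC20 fell from 168 ± 6.78 to 34.4 ± 0.0456 FPKM (-2.25, adjusted p = 7.95e-06), along with KRTAP2-3 (-2.43), MYBL2 (-2.34) and THBS1 (-2.17). RNA45SN5, whose call met the rule for named genes in both arms, was listed at 0 in all day 4 libraries. All 26 NF-kB and inflammatory genes rose (median 1.88, camera adjusted p = 1.91e-10; adjusted p = 0.175 with an estimated correlation). Extracellular matrix and TGF-beta targets had 24 rises and 1 fall of 31 (camera adjusted p = 4.39e-07), and this list alone kept its call with an estimated correlation (adjusted p = 0.0338). Of 8 fibroblast markers, of which COL1A1 and LUM belong to the matrix list as well, 6 rose (median 0.54, camera adjusted p = 0.0432; adjusted p = 0.305 with an estimated correlation). This call was lost with a pseudocount of 0.1 (0.0572), no filter (0.164), a filter of 5 FPKM (0.793), quantile normalization (0.115), median ratio scaling (0.0519), TPM (0.0514) and without genes holding CATTTC (0.08). It was also lost without shNT day 2 replicate 1 (0.0554), shIno80 day 2 replicate 1 or 2 (0.0504 each) or shNT day 4 replicate 1 (0.0585). Interferon-stimulated genes had 31 rises and 2 falls of 39 (camera adjusted p = 4.18e-06; adjusted p = 0.407 with an estimated correlation). All 40 mitosis genes (median -1.62, camera adjusted p = 3.64e-11; adjusted p = 0.407 with an estimated correlation) and all 42 replication genes (median -1.41, camera adjusted p = 1.71e-12; adjusted p = 0.394 with an estimated correlation) fell. Heat shock genes had 15 falls of 16 (camera adjusted p = 8.47e-08; adjusted p = 0.16 with an estimated correlation). Adjusted over the list alone, 25 matrix genes rose, and the other counts given here were the same. In all 8888 genes changed (69.1%), 4160 up and 4728 down (5188 and 4829 with no filter), 762 and 524 of them at least 2-fold; camera called 10 lists up and 14 down, 1 of them with an estimated correlation, and fry 33.

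In shIno80 cells mitosis and replication genes fell and interferon-stimulated genes rose with time. From day 2 to day 4 MMP10 rose from 0.523 to 60.0 FPKM (log2 change 5.31, adjusted p = 9.12e-07), PI3 by 5.22, IL1B from 3.21 to 91.5 FPKM (4.38), BMP6 from 2.48 to 68.2 FPKM (4.32) and SERPINB7 from 3.64 to 68.5 FPKM (3.88). The mitotic kinesin KIF20A fell from 40.1 to 4.08 FPKM (-3.04), MYBL2 by a log2 change of -3.03, CDC20 from 118 ± 0.313 to 14.4 ± 4.92 FPKM (-2.98) and the serine synthesis enzyme PHGDH from 88.3 to 11.2 FPKM (-2.88). All 40 mitosis genes (median -2.36, camera adjusted p = 2.52e-15; adjusted p = 0.315 with an estimated correlation) and all 42 replication genes (median -1.58, camera adjusted p = 1.23e-14; adjusted p = 0.315 with an estimated correlation) fell. Interferon-stimulated genes rose in 36 of 39 cases (median 1.23, camera adjusted p = 2.74e-08; adjusted p = 0.315 with an estimated correlation) and NF-kB genes in 22 of 26 (median 1.45, camera adjusted p = 3.14e-07; adjusted p = 0.315 with an estimated correlation). Oxidative phosphorylation genes had 41 falls and 1 rise of 49 (camera adjusted p = 4.44e-09; adjusted p = 0.365 with an estimated correlation). In counts adjusted over the list alone 23 NF-kB genes rose and 42 oxidative phosphorylation genes fell. In all 8804 genes changed (68.5%), 4640 up and 4164 down, 742 and 575 of them at least 2-fold; camera called 8 lists up and 14 down, and 0 with an estimated correlation (5 at an unadjusted p under 0.05), against 34 by fry. In both arms 3315 genes rose and 3438 fell (1501 and 1531 if independent), 105 rose in shNT and fell in shIno80 cells, and 168 did the reverse. The values if independent again do not allow for the shared spread estimate. Under TPM, which took the median of all genes from 0.029 to 0.17, 5930 genes rose and 3057 fell; 4216 rose and 4553 fell under quantile normalization, and 3389 and 3523 with a filter of 5 FPKM. The change with time differed between the arms, by the test of the day 4 effect minus the day 2 effect, for 2843 genes by limma (4150 under TPM; 1352 and 1717 without shNT day 2 replicates 1 and 2, 1584 and 1514 without shIno80 day 2 replicates 1 and 2, 1891 without shIno80 day 4 replicate 1) and for 9 lists by camera (0 with an estimated correlation, 2 at an unadjusted p under 0.05; 15 by fry), with a median of -0.73 for mitosis.

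Genes whose 3′UTR matched 1 short sequence were lower in shIno80 cells. The sequence was found in these data: of 15484 sequences of 7 bases scored in 5686 genes, CCATTTC went with the lowest day 2 changes (score -10.6, next unrelated sequence -4.1). In the 5686 genes not used to find it, though they had been part of an earlier look at all genes, the 272 genes with the 8-base match CCATTTCA were lower on day 2 than the 3303 genes without a match by a mean log2 difference of -0.22 (SE 0.027). The difference was -0.14 (SE 0.016) for the 603 genes matching CCATTTC only, -0.090 (SE 0.014) for the 655 genes matching CATTTCA, and -0.008 (SE 0.012) for the 853 genes matching only the 6 bases CATTTC. For all matches of 7 or 8 bases together it was -0.13 (1530 against 3303 genes, two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). The 8-base difference was -0.23 (SE 0.029) on day 3 and -0.22 (SE 0.030) on day 4; for the change with time in shNT cells it was 0.024 (SE 0.038). Such a match lay in 1117 of the 2600 searched genes lowered on day 2 (43%), in 65.0% of those lowered at least 2-fold (67 of 103), in 19.5% of the raised genes and in 22.6% of genes not called. On day 4 it lay in 33.8% of the lowered genes. These shares, like those of the gene lists above, are over all genes searched, including the 5686 used to find the sequence. They are not adjusted for 3′UTR length. INO80 mRNA held 2 matches of 8 bases in its 6365 bases, none of them in its 3′UTR; 16.1% of the 628 transcripts of similar length hold at least 1. A second sequence, GAAGAGCA, went with higher values: the 214 genes with it in the 3′UTR were above the 4076 genes without a match by 0.091 (SE 0.024) on day 2. Its first 7 bases, GAAGAGC, scored 4.9 against 4.2 for the next unrelated sequence. Among genes without a match in the 3′UTR, those with the 8 bases elsewhere in the transcript differed by 0.053 (SE 0.012) on day 2 and 0.072 (SE 0.016) on day 4 for GAAGAGCA, and by -0.074 (SE 0.022) and -0.081 (SE 0.035) for CCATTTCA. From day 2 to day 4 the genes with GAAGAGCA elsewhere moved by -0.141 (SE 0.023) in shNT and -0.114 (SE 0.024) in shIno80 cells, and those with it in the 3′UTR by 0.024 (SE 0.039) in shNT cells. The genes with CCATTTCA elsewhere moved by -0.099 (SE 0.043) in shNT and -0.106 (SE 0.047) in shIno80 cells. Values for matches elsewhere were not adjusted for the length or base composition of that part of the transcript. Of the genes named above, MITF, JUN, HMGA2, NR4A2, MYOF, MAD2L1, PHLDA3, BCL2L2, IFIT5, STAT2, HERPUD1, BANF1, ARHGAP19, PLOD2 and SERPINB7 also held a 7- or 8-base match to CCATTTCA in the 3′UTR. Without any gene holding the 6 bases CATTTC, an alternative chosen after seeing the data, 8110 genes were tested. Of these, 2746 changed on day 2 (1619 up, 1127 down) and 5545 averaged over days (3191 up, 2354 down). With all 12857 genes tested, 5210 and 9113 changed.

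**Figure D5:**
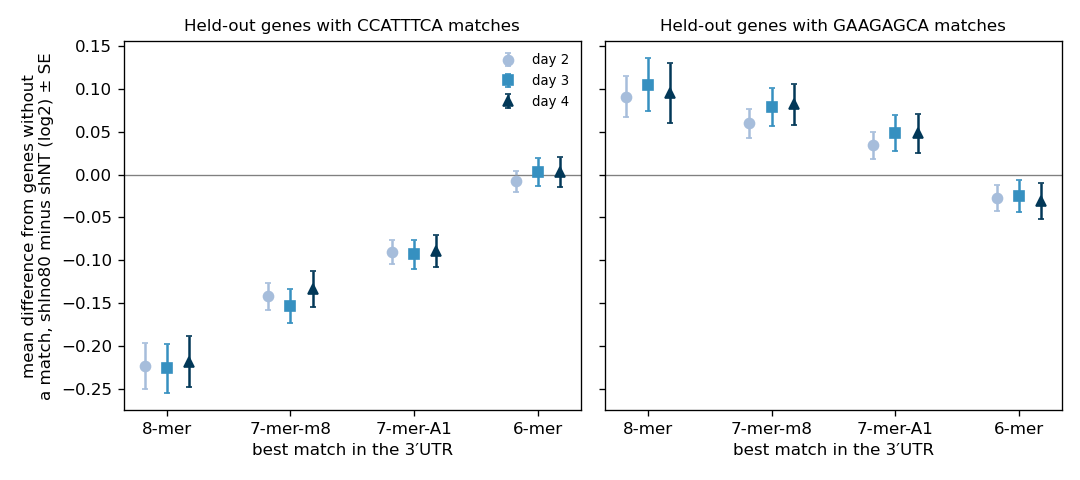
Mean log2 difference (with SE over genes) between genes with and without a 3′UTR match, by match type and day, in genes not used to find the sequence. On day 2 the 8-base match to CCATTTCA stands at -0.22 and the 6-base match at -0.008.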

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

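The tests of the 3′UTR sequences were chosen only after the result was seen, as was the use of quantile normalization and median ratio scaling, both planned as alternatives, to test a cause. The other tests with set bounds were chosen before their result was seen. The split of the mitosis and replication genes below nevertheless uses CATTTC, which was found in these data.

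Genes with a 3′UTR match to CCATTTCA were lower in shIno80 cells, and genes matching GAAGAGCA were higher. A candidate explanation is that the guide strand of the shIno80 hairpin acted like a microRNA through its seed: in genes not used to find the sequence, though part of an earlier look at all genes, the day 2 difference was -0.223 for 8-base matches and was graded by match length down to -0.008 for the 6-base match. Whether base composition alone gives this was not settled. Of the other 8-base sequences made of the same bases, 0 gave a difference as low (-0.21 against a lowest other value of -0.208, a narrow margin). That comparison cannot decide, since it used all genes searched, among them those in which the sequence was picked as the lowest. Genes without a 3′UTR match that held CCATTTCA elsewhere in the transcript were lower too, by -0.074 (SE 0.022), and moved with time by -0.099 (SE 0.043) in shNT and -0.106 (SE 0.047) in shIno80 cells. The mirror pattern, 0.091 for GAAGAGCA, may reflect the seed of the shNT hairpin in the same way. Of 279 other sequences of the same bases, 0 were as high (0.106 against 0.095, a narrow margin). That comparison also included the genes in which the sequence was picked as the highest, so it cannot decide. Genes that held GAAGAGCA outside the 3′UTR alone were higher too, by 0.053 (SE 0.012), and moved with time by -0.141 (SE 0.023) in shNT and -0.114 (SE 0.024) in shIno80 cells. The differences for matches outside the 3′UTR were not adjusted for the length or base composition of the rest of the transcript. No conclusion is drawn from them. A loss of INO80 itself that acts on these genes cannot be told apart, since over all genes searched the 8-base difference moved by only -0.008, from -0.238 on day 2 to -0.246 on day 4, and the hairpin sequences are not in the labels.

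Mitosis and replication genes were lower in shIno80 cells. Repression of these genes through their own 3′UTR matches is argued against: the 56 members without the 6-base match had a median averaged change of -0.536 (MAD 0.255), and 50 of them fell. The shIno80 libraries may instead lie further along the course that shNT cells follow with time, which cannot be told apart: across genes the day 3 shIno80 change followed the shNT change from day 2 to day 4 with Spearman rho 0.31 (Pearson r 0.204), between the bounds set for and against. NF-kB genes, all 26 of which rose in shNT cells, had 5 rises and 12 falls in shIno80 cells on day 3 (median -0.235). A shift along that course would not give this for these genes, but no bound was set for this comparison beforehand. Heat shock genes went the same way in both, lower with time in shNT cells and lower averaged over days in shIno80 cells. Loss of INO80 and repression of some other gene by the hairpin both stay open as causes and were not tested apart, since 1 hairpin was used.

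Ribosomal protein genes were higher on day 2 and lower on day 4 in shIno80 cells, a change in the effect of -0.453 (MAD 0.192). A wrong scale factor per library is argued against, since median ratio scaling left it at -0.504 (SE over genes 0.033). Under quantile normalization it was -0.097, which met the bound set for a cause in the shape of each library's distribution. That test was judged void only after its value was seen, since 57 of the 100 most abundant genes are ribosomal protein genes and the method removes a joint change of such genes by construction, so this explanation cannot be told apart. A loss of short or abundant transcripts in general cannot be told apart either: 72 other genes matched on length and FPKM moved by -0.127 (MAD 0.416), but they were longer (2088 against 975.5 bases) and less abundant (448 against 1350 FPKM).

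Averaged over days 9113 genes changed, and 1 of the 100 splits of the libraries within days that were drawn (of 108 possible) gave as many, the real one. The highest other split gave 6228 genes; it kept the labels on day 2 and exchanged all of them on days 3 and 4.

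The following results stood out because the shIno80 effect differed between days, by a test of the difference itself. By the F test 1743 genes differed between the 3 days, with 339 and 558 without shNT day 2 replicates 1 and 2, 479 and 438 without shIno80 day 2 replicates 1 and 2, 1005 and 1101 without shNT day 3 replicates 1 and 2, 985 and 1027 without shIno80 day 3 replicates 1 and 2, and 1072 without shIno80 day 4 replicate 1. Between days 2 and 4, 2843 genes differed (1783 up, 1060 down; 1257 and 1311 under median ratio scaling, 1351 and 1342 under quantile normalization, 3464 and 686 under TPM), so that the excess of rises depended on the scaling. The count was 1352 and 1717 without shNT day 2 replicates 1 and 2, 1584 and 1514 without shIno80 day 2 replicates 1 and 2, and 1891 without shIno80 day 4 replicate 1. Between days 2 and 3, 61 genes differed (24 up, 37 down). The F test over the 3 days called more genes under TPM (3041) and with the replicate number as a block (2680).

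For gene lists, the median effect of day 4 minus that of day 2 was -0.453 for ribosomal proteins, -0.53 for glycolysis, -0.274 for oxidative phosphorylation and -0.729 for mitosis (camera adjusted p from 8.66e-24 to 1.79e-10). It was 0.372 for interferon-stimulated genes (adjusted p = 0.00631), 0.245 for heat shock (0.00843), -0.271 for NF-kB (0.0197), 0.229 for apoptosis regulators (0.0246) and 0.13 for SWI/SNF, ISWI and CHD remodellers (0.0299). With an estimated correlation adjusted p ran from 0.232 to 0.77 over these lists, and fry did not call mitosis (0.0925), interferon-stimulated genes (0.0925) or NF-kB (0.18). Without shIno80 day 4 replicate 2 the calls for interferon-stimulated genes (0.109), NF-kB (0.059) and remodellers (0.122) were lost, and without shNT day 4 replicate 1 those for interferon-stimulated genes (0.0796) and remodellers (0.0748). Without shIno80 day 2 replicate 1 the calls for NF-kB (0.0835), apoptosis regulators (0.0542) and remodellers (0.0835) were lost, and without shNT day 2 replicate 2 that for NF-kB (0.26). The call for remodellers was also lost with a pseudocount of 5 (0.0571), a filter of 5 FPKM (0.0731), quantile normalization (median 0.05, 0.323) and median ratio scaling (median 0.081, 0.0645). Without genes holding CATTTC in the 3′UTR, an alternative chosen after the result was seen, 8110 of the 12857 genes were tested and 4 calls were lost. The medians were then 0.162 for remodellers (0.0645), -0.204 for NF-kB (0.232), 0.159 for heat shock (0.276) and 0.175 for apoptosis regulators (0.232).

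For named genes the log2 effect of day 4 minus that of day 2 was positive for MMP10 (3.037), SERPINB7 (3.035), APOD (2.228), JUN (1.528), ARHGAP19 (1.269), BMP6 (1.203), CEACAM1 (1.181), HERPUD1 (1.073), DSP (1.044), B2M (0.68), HSP90AA1 (0.508), BANF1 (0.467), PHLDA3 (0.423), SMARCD1 (0.33), COL6A1 (0.317), MORF4L1 (0.291) and PARP2 (0.213). It was negative for KRT81 (-2.827), APOE (-2.269), IL37 (-1.981), TXNIP (-1.634), CXCL1 (-1.634), EEF1A2 (-1.619), PLOD2 (-1.22), RPL22 (-1.164), PHGDH (-1.085), KIF20A (-1.063), RPL7A (-0.997), C3 (-0.829), FAP (-0.767), FADS1 (-0.758), RPL35 (-0.728), CAV1 (-0.706), NR4A2 (-0.683), LIF (-0.648), COX7C (-0.618), FAM162A (-0.61), ENO1 (-0.582), RPL13A (-0.535), COL5A1 (-0.534), ME1 (-0.523), TFAP2C (-0.509), CD55 (-0.453), LOXL2 (-0.44), SREBF2 (-0.399), PPT1 (-0.381), PSAT1 (-0.367), INO80 (-0.359), TGFBI (-0.284) and NDUFA9 (-0.238). Each of these genes passed the F test.

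Accessions without a gene symbol were not part of the gene values. Tested on their own, 113 of 267 changed averaged over days, 67 up and 46 down, 4 of them at least 2-fold, in data the comparisons did not use. Of all 19048 accessions tested in the same way 10481 changed, a larger share.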

How the results depend on the processing

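The alternatives without small RNA genes, without genes holding the 6 bases CATTTC in the 3′UTR, per accession and without the 2 libraries with the highest small RNA share were chosen only after the result was seen. Averaged over days, INO80 fell under each alternative of pseudocount, filter, scaling, block and variance model, from -0.974 (pseudocount 5) to -2.114 (pseudocount 0.1) and from -1.728 to -1.70 with 1 library left out. Named genes were chosen mostly for a large change or a small p-value in these data, which favours keeping a call under the alternatives. Of 224 results for named genes in a contrast, 217 passed the threshold. Of these, 215 did under each of the same alternatives and with each library left out, wherever the gene was tested (206 of the 224 with a filter of 5 FPKM); PI3 on day 3 and SERPINB2 on day 2 did not. The lone library of a group with 1 left out is assumed to vary like the other groups, and with no counts in the files the limit set by depth was not measured.

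With a 2-fold threshold, which removes smaller changes by construction, the counts were 154 on day 2, 394 on day 3, 528 on day 4, 261 averaged over days, 1286 in shNT over time and 1317 in shIno80 over time. Without CATTTC genes 8110 genes were tested in place of 12857, and 2746, 4117, 4568 and 5545 changed on days 2, 3 and 4 and averaged. With 1 library left out the day 2 count ran from 3387 (without shNT day 2 replicate 1; 3412 without shIno80 day 2 replicate 2) to 5558. The F test called 3041 genes under TPM, 2680 with the replicate number as a block, and 339 (without shNT day 2 replicate 1) to 1897 with 1 library left out. The block gave 9474 genes averaged over days. The cause was not tested. Under TPM the median of all genes was 0.132 on day 4, 0.173 in shIno80 over time and 0.173 for day 4 minus day 2, against 0.037, 0.029 and 0.048 as deposited.

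Pearson r between days 2 and 3, 2 and 4, and 3 and 4 was 0.416, 0.443 and 0.437 with a pseudocount of 0.1, 0.435 and 0.434 for the first pairs with no filter, and 0.847, 0.69 and 0.882 without small RNA genes. With 1 library left out it ran from 0.415 to 0.494, from 0.407 to 0.492 and from 0.424 to 0.525. The cause was not tested.

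Of the 38 lists averaged over days, 15 were called by camera, 0 with an estimated correlation, 32 by fry, which does not compare a list with other genes, and 10 without CATTTC genes. The SRCAP and TIP60 list turned to the direction down by fry, with a median of 0.114 averaged over days and 0.123 on day 3. Oxidative phosphorylation in shNT over time turned to a median of 0.045 under quantile normalization (adjusted p = 0.543; -0.13 and 0.0427 as deposited). The cause was not tested.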

Other observations

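All tests in this part follow the contrasts fixed before, and no test was chosen only after the result was seen. In shNT cells pigmentation and antigen presentation genes were higher on day 4 than on day 2. Of 13 measured pigmentation genes 9 rose and 2 fell from day 2 to day 4 (camera adjusted p = 0.0338; adjusted p = 0.184 with an estimated correlation; 0.189 with a filter of 5 FPKM and 0.0986 under quantile normalization), and of 7 antigen presentation genes 5 rose (adjusted p = 0.0229; adjusted p = 0.175 with an estimated correlation). SOX10 rose (log2 change 0.56, adjusted p = 4.7e-05), and CD68, a lysosomal protein also used as a macrophage marker, rose by 2.18 (adjusted p = 1.06e-05). Chromatin genes fell: 18 of 23 SWI/SNF, ISWI and CHD remodellers (adjusted p = 0.000849; adjusted p = 0.305 with an estimated correlation), 14 of 17 SRCAP and TIP60 subunits (adjusted p = 0.00212; adjusted p = 0.16 with an estimated correlation) and 10 of 15 INO80 complex subunits (adjusted p = 0.00975; adjusted p = 0.16 with an estimated correlation). Counts adjusted over the list alone were the same for these 5 lists.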
